A study of mouse gut metagenome with 48 samples.

How the data were processed

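The bacterial 16S rRNA gene (variable region V4) was sequenced on an Illumina MiSeq from gut samples of C57BL/6J mice kept for 31 days at 6 °C (cold) or at room temperature. Fresh feces were taken at days 0, 11 and 31, and cecal content at day 31. Per the labels, the DNA of the fecal samples was extracted with the QIAamp Fast DNA Stool Mini Kit. The series text names that kit for feces and cecum alike, whereas the extraction protocol states that the 9 cecal specimens went to a service laboratory, where a MoBio PowerMag kit was used. Site and DNA isolation are therefore confounded in every comparison of cecum with feces. Each sample was amplified with 2 barcoded V4 primers, and how the reads of both were combined is not given in the sources used here.

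The deposited table holds counts of reads per operational taxonomic unit (OTU), which the authors made with QIIME and their own scripts. They filtered reads by quality, assigned them to samples by exact barcode, searched them against Greengenes and clustered them at 97% identity with uclust. The longest sequence of each OTU was classified with the Bayesian classifier of Mothur, trained on Greengenes clustered at 98%. The versions of these tools are not given in the sources used here. Taxon labels such as 91otu805 are Greengenes cluster labels that carry no taxon name. OTUs of this kind are given by their phylum only.

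The table has 2590 OTUs in 48 libraries, 39 from feces and 9 from cecum, and all 48 were used. The labels speak of 49 samples sent for sequencing. Every library sums to 86876 reads, so the libraries appear to have been subsampled to a common depth, which the labels do not state. At this depth a count of 0 allows a share of up to 0.00345% of a library, taken as 3 reads. This floor, and the 95% Wilson intervals given for shares of single libraries, cover counting error only, since reads from PCR are not independent molecules. The labels call each sample an individual biological replicate and name no cage. Mice of a cage share bacteria, so cage and temperature could be confounded, and the p-values below measure the spread between samples only.

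Cold and room temperature were compared in feces at days 0, 11 and 31 and in cecum at day 31. Days 11 and 31 were compared with day 0 within each temperature, cecum was compared with feces at day 31 within each temperature, and the interactions of temperature with time and with site were tested. The groups, comparisons, tests, thresholds, taxon lists, the rule for naming OTUs and most of the alternatives were fixed before the data were examined.

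OTU counts were tested with the edgeR quasi-likelihood test (version 4.0.16) on the groups compared, after TMMwsp scaling. OTUs were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over the OTUs tested, with a threshold of 0.05. Standard errors of log2 fold changes (SE) were computed from the fold change and its test statistic. Up to 8 OTUs per direction (temperature) or 4 per direction (time and site) with the largest mean share among those past the threshold were examined by name, and the text gives a selection of them.

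Shares of phyla, families and genera with a mean of at least 0.1% in 1 or both of the groups compared were tested with exact two-sided permutation tests of the difference of means, adjusted over the taxa of that rank. The fixed lists held 9 phyla and 29 families. Further lists were mucin degraders (Akkermansia), Clostridiales that make short-chain fatty acids (Lachnospiraceae and Ruminococcaceae), butyrate-linked genera (Roseburia, Butyricicoccus, Faecalibacterium, Coprococcus, Anaerostipes, Eubacterium and Oscillospira), sulfate reducers (Desulfovibrionaceae), and lactic acid bacteria (Lactobacillus, Enterococcus, Streptococcus and Lactococcus). There were also lists of facultative anaerobes and pathobionts (Enterobacteriaceae, Helicobacteraceae, Alcaligenaceae and Enterococcaceae), plant and host organelles, diet-borne Lactococcus, and taxa known from reagents. The log2 ratio of Firmicutes to Bacteroidetes reads, the number of OTUs per library and the Shannon index were tested in the same way. Community composition was tested by permutational analysis of variance on Bray-Curtis distances, with exact enumeration of the splits.

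The sample numbers were checked as pairs by the correlation of OTU profiles. Cecum and feces of the same number paired, so paired values stand beside the site results. Between temperatures and across days the numbers were not shown to pair. Day 31 and day 0 at room temperature had the lowest p across days. The mean correlation was 0.134 for the same number against -0.0269 for others (one-sided permutation p = 0.0361). Day 31 and day 11 in cold had the highest mean correlation across days, 0.145 against -0.0219 (one-sided permutation p = 0.0532). For day 31 and day 0 in cold it was -0.0828 against 0.0119 (one-sided permutation p = 0.915). Only 1 of these 7 pairs correlated best with its own number. Pairing across days therefore stayed open. The change from day 0 per number was kept as planned and rests on the labels' numbering. No library was a copy of another of its group, as the lowest chi-square per degree of freedom over the 126 pairs within groups was 32.7. Pairs across groups were not checked.

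Alternatives were plain TMM, library totals only, DESeq2 (1.42.0), no filter, a minimum count of 50, a single fit over all 8 groups, blocks by number or by animal, centred log-ratios with a pseudocount of 0.5, shares outside Verrucomicrobia, taxa of any share, edgeR on counts summed per taxon, other measures of diversity and distance, and leaving out each library in turn. Chosen after the data were seen were richness at 43438 reads, the exact test of cecum minus feces per number, the alternatives for single taxa, folds, mean shares and mean changes with 1 library or number left out, and leaving out libraries in the interactions with time and in the change from day 0.

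The OTU test was tried on simulated data with known changes. At the size of the day 31 comparison it recovered 63.6% of OTUs changed 16-fold and 0% of those changed 4-fold, with no false call. This was 1 simulated run, whose spread was estimated over all OTUs before the filter and without scaling. It therefore does not set the detection limit of the real data. In simulations without a difference at the sizes of day 31, day 11 and cecum, the permutation test gave an unadjusted p under 0.05 in 5.6%, 5.6% and 4.9% of tests. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and vegan 2.7.1.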

Results

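The series asks what part the gut bacteria of mice play in energy balance during prolonged cold, and its labels set cold against room temperature over time. Bacterial 16S rRNA gene reads were counted in 39 fecal and 9 cecal libraries. Feces came from 7 cold and 6 room temperature mice at day 0, from 7 and 5 at day 11, and from 8 and 6 at day 31. Cecal content came from 5 cold and 4 room temperature mice at day 31. Each library held 86876 reads, spread over 474 to 946 OTUs. The 622 OTUs with at least 100 reads held 99.4% of the 4170048 reads. A named family was assigned to 78.7% of the reads and a named genus to 21.5%, so most statements are made at the rank of family or phylum. Values are means ± SD over libraries, as shares of a library's reads, unless stated.

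**Figure D1:**
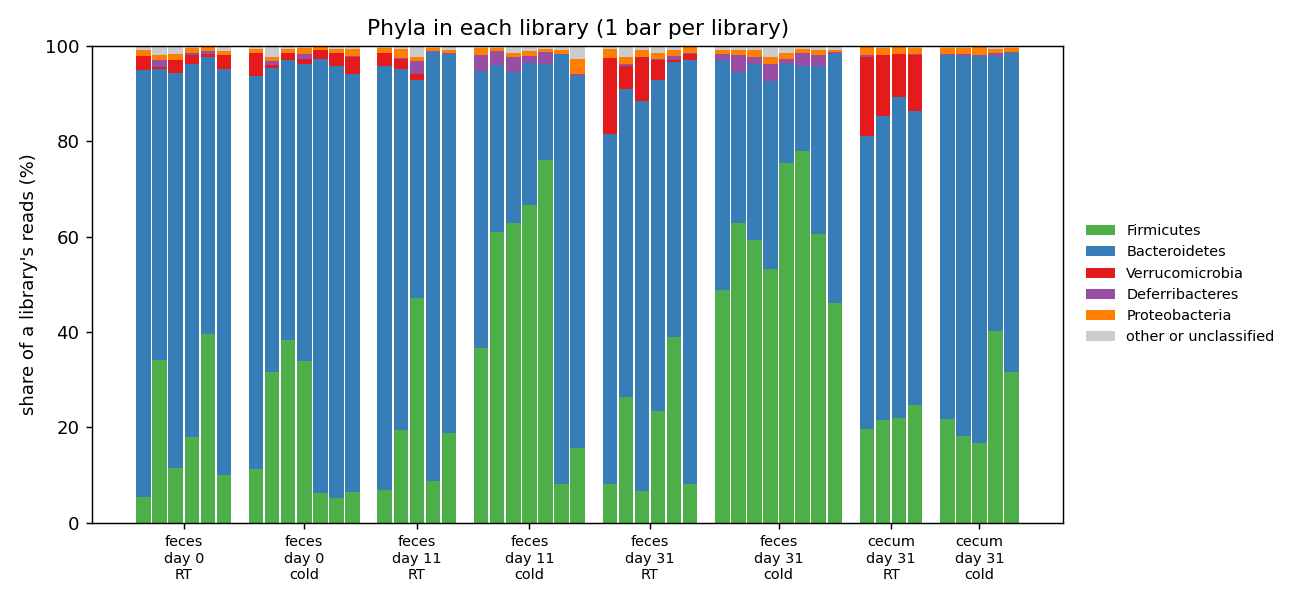
Each bar is 1 library and shows the share of its reads (%, vertical axis) held by 5 phyla, with the 8 groups along the horizontal axis. In feces at day 31, Firmicutes held 60.5% of reads on average in cold and 18.6% at room temperature, while Verrucomicrobia held 0.00216% and 5.96%.

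At day 0, the start of the 31 days, no difference was detected between the groups assigned to cold and to room temperature. Bacteroidetes held 76.6% ± 14.4 of reads in the group assigned to cold (n = 7) and 75.8% ± 13.1 in the other (n = 6; exact permutation p = 0.876, two-sided). Firmicutes held 19.0% ± 14.8 and 19.8% ± 14.0, and Verrucomicrobia 2.29% ± 1.48 and 1.89% ± 1.16. S24-7, a Bacteroidetes family abundant in mice, held 49.0% ± 14.9 and 48.5% ± 14.8. Erysipelotrichaceae, at 0.0858% and 0.276%, came closest to a difference among the 36 families (exact permutation p = 0.0186, adjusted p = 0.671, and 0.280 adjusted over the list alone). Its genus Allobaculum held 0.0480% ± 0.0634 (0.0255% without cold 1) and 0.240% ± 0.178 (exact permutation p = 0.0210, adjusted p = 0.776). The genus cluster 94otu4519, which has no name, came closest among genera, at 0.933% ± 0.617 and 0.215% ± 0.199 (exact permutation p = 0.0035, adjusted p = 0.259). By the exact permutation test, 0 of 7 phyla, 0 of 36 families and 0 of 74 genera passed adjustment, with 0, 1 and 2 at an unadjusted p under 0.05, and edgeR on summed counts also gave 0 families. None of the 15 fixed families passed when adjusted over the list alone. Among 218 OTUs tested with edgeR, 0 passed, with 8 at an unadjusted p under 0.05 and 0 by DESeq2. The log2 ratio of Firmicutes to Bacteroidetes was -2.44 ± 1.55 and -2.25 ± 1.36 (exact permutation p = 0.838), a difference whose sign turned in 5 of the 13 leave-outs of 1 library. The community R2 was 0.0580 (exact permutation p = 0.692).

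After 11 days, Verrucomicrobia, whose reads here were all of the mucin-degrading genus Akkermansia, were 322-fold lower in cold feces. They held 0.00395% ± 0.00318 of reads in cold (24 reads in 7 libraries) and 1.27% ± 1.24 at room temperature (5527 reads in 5 libraries), and 6 of 7 cold libraries lay below every room temperature library. Room temperature 5 and 6 held only 19 and 7 Akkermansia reads, near the 0 to 9 of the cold libraries. Lactobacillaceae, a family of lactic acid bacteria, held 0.00855% ± 0.00598 and 0.197% ± 0.315, a share 23.1-fold lower in cold, and 6.73-fold without room temperature 2. Firmicutes held 46.7% ± 26.7 in cold and 20.2% ± 16.1 at room temperature (13.5% without room temperature 3), and Bacteroidetes 49.0% ± 26.8 and 76.0% ± 18.0, and these differences lay within the spread of the libraries (exact permutation p = 0.0833 and 0.0859, two-sided). S24-7 held 25.8% ± 17.8 and 53.5% ± 18.0, and Lachnospiraceae 5.12% ± 3.04 and 1.54% ± 0.881, and neither passed adjustment (adjusted p = 0.138 and 0.0842). On centred log-ratios Lachnospiraceae (adjusted p = 0.0361) and Desulfovibrionaceae (0.0473, and 0.162 on shares) passed, both higher in cold. Cyanobacteria held 0.683% and 0.421% and passed only without room temperature 3 (adjusted p = 0.0424), when the room temperature mean was 0.181%.

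The difference of Verrucomicrobia at day 11 passed the exact test (p = 0.00505, adjusted p = 0.0354 over 7 phyla). Of 50 families tested, 4 were higher and 4 lower in cold. Among them were 2 of the 15 fixed families tested, Verrucomicrobiaceae and Lactobacillaceae, both lower (adjusted p = 0.0473 each), and 0 passed when adjusted over the list alone, with 14 of the 50 at an unadjusted p under 0.05. By edgeR on summed counts 3 fixed families were lower, Erysipelotrichaceae being the other one. Among genera with a name, Akkermansia, Allobaculum and Lactobacillus were lower, and Allobaculum had 1 read in the 7 cold libraries against 1760 in the 5 others, 1253 of these in room temperature 2 (adjusted p = 0.0379, 0.0281 and 0.0379). The lists of mucin degraders and of lactic acid bacteria were lower in cold (adjusted p = 0.0455 each), the latter at 0.0102% ± 0.00649 against 0.198% ± 0.316 (0.0581% without room temperature 2). Most of these calls needed every library or nearly every one. For the phylum, adjusted p reached 0.0848 without cold 1, 2, 4, 6, 7 or 8 or room temperature 1, 2 or 5, and for its genus 0.0874 without cold 2, 4, 6 or 8 or room temperature 1, 2, 3, 5 or 6. Verrucomicrobiaceae failed without any 1 library (adjusted p up to 0.109), and Lactobacillaceae without any 1 of the 11 others (up to 0.0990) and on centred log-ratios (0.0583), while without room temperature 2 its mean fell under the minimum share. Lactobacillus failed without cold 2, 3, 4, 6, 7 or 8 or room temperature 1, 3, 5 or 6 (up to 0.0918), and Allobaculum without room temperature 1, 2, 5 or 6 (up to 0.0673). The list of mucin degraders failed without any library but cold 3 and room temperature 6, and that of lactic acid bacteria without any but room temperature 6 (up to 0.109 each).

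Among 275 OTUs tested at day 11, 12 were higher and 15 lower in cold, including 0 higher and 7 lower of 86 in Bacteroidetes, and 12 higher and 8 lower of 182 in Firmicutes. The Firmicutes OTU259820 was higher by 8.28 ± 2.05 (log2, SE), with 2.37% ± 5.51 of reads in cold and 0.00599% at room temperature. Cold 6 held most of these reads, and without it the difference was 5.3 and the cold mean 0.290%. Lower in cold were the S24-7 OTU277364 by -3.55 ± 0.953, the S24-7 OTU801260 by -8.79 ± 1.33, and the Firmicutes OTU180944 by -8.22 ± 1.56 on the same scale (-6.67 without room temperature 6). The mucin-feeding species Ruminococcus gnavus (OTU2897332) was higher by 4.08 ± 1.1, a call lost without room temperature 1, 3, 5 or 6 (3.53 to 4.03). The log2 ratio of Firmicutes to Bacteroidetes was -0.23 ± 2.00 in cold and -2.21 ± 1.48 at room temperature (exact permutation p = 0.0985), and passed without cold 7 (2.53, exact permutation p = 0.0303) or as Lachnospiraceae plus Ruminococcaceae over S24-7 (2.66, exact permutation p = 0.048). The count of 27 fell to 14 without room temperature 1 and to 15 without cold 4, and DESeq2 called 66. The community R2 was 0.247 (exact permutation p = 0.0177, adjusted p = 0.0236), but 0.239 on family shares (p = 0.0543) and 0.211 without room temperature 1 (p = 0.0515). The mean Bray-Curtis distance was 0.590 between the groups, 0.574 within cold and 0.385 within room temperature. With groups of unequal spread and size, this test cannot tell a wider scatter in cold from a shift of composition.

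After 31 days, fecal Firmicutes were 3.25-fold higher in cold, at 60.5% ± 11.6 of reads (n = 8) against 18.6% ± 13.1 at room temperature (n = 6). Bacteroidetes held 35.3% ± 12.0 in cold and 72.7% ± 11.3 at room temperature. Verrucomicrobia were 2761-fold lower in cold, with 15 reads in 8 libraries (0.00216% ± 0.00168) against 31057 reads in 6 (5.96% ± 5.75). The cold mean lay under the floor of 3 reads per library, so the size of this fold is uncertain. Deferribacteres, here the mucus-dwelling genus Mucispirillum, were 9.56-fold higher at 2.10% ± 1.19 against 0.219% ± 0.276, and 17.4-fold without room temperature 5. Proteobacteria held 0.992% ± 0.271 in cold and 1.46% ± 0.203 at room temperature.

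All 8 cold libraries lay above every room temperature library for Firmicutes, and below every one for Bacteroidetes and Verrucomicrobia (exact permutation p = 0.000666, the smallest possible, adjusted p = 0.00155, two-sided). For Deferribacteres 7 of 8 lay above (adjusted p = 0.0035) and for Proteobacteria 6 of 8 below (adjusted p = 0.00373). These 5 of 7 phyla kept their call with any 1 library left out. On centred log-ratios the difference of Bacteroidetes was -0.122 and no longer passed (adjusted p = 0.813), while that of Proteobacteria turned to 0.234 (adjusted p = 0.371). These ratios are taken against the mean over the 7 phyla, which the near absence of Verrucomicrobia lowers in cold. Over families, S24-7 (-1.70, exact permutation, adjusted p = 0.0212) and Bacteroidaceae (-1.17, adjusted p = 0.0366) stayed lower in cold on centred log-ratios. Odoribacteraceae and Porphyromonadaceae passed as lower too, while Prevotellaceae and Rikenellaceae did not pass. Tenericutes did not pass, nor did Cyanobacteria, at 0.545% and 0.361%. The log2 ratio of Firmicutes to Bacteroidetes was 0.84 ± 0.815 in cold and -2.28 ± 1.29 at room temperature, an 8.67-fold difference in the ratio (exact permutation p = 0.000666, the smallest possible, adjusted p = 0.00266).

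**Figure D2:**
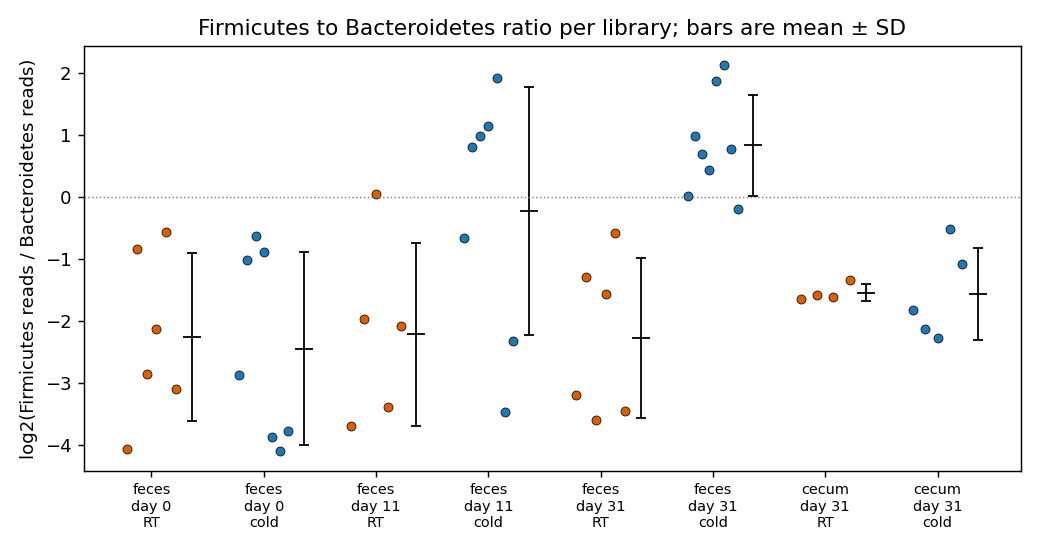
The vertical axis gives the log2 ratio of Firmicutes to Bacteroidetes reads, with 1 point per library (orange, room temperature; blue, cold), group means and SD as bars, and the 8 groups along the horizontal axis. Cold feces at day 31 averaged 0.84 against -2.28 at room temperature, while cecal content averaged -1.56 and -1.54.

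At the rank of family at day 31, members of Clostridiales with many fiber fermenters were higher in cold. Lachnospiraceae held 4.68% ± 1.38 in cold (n = 8) and 1.3% ± 0.661 at room temperature (n = 6), a 3.56-fold difference, and Ruminococcaceae 16.7% ± 5.96 and 4.84% ± 4.29, a 3.46-fold difference. S24-7 was 2.84-fold lower, at 19.0% ± 9.04 in cold and 53.9% ± 11.0 at room temperature. Lower in cold too were Alcaligenaceae, at 0.133% ± 0.0581 against 1.02% ± 0.433 (7.66-fold), Porphyromonadaceae, at 0.0105% ± 0.0113 against 0.158% ± 0.101 (15-fold), and Erysipelotrichaceae, at 0.0271% ± 0.0166 against 0.659% ± 0.662 (24.4-fold). Rikenellaceae (9.37% in cold, 9.60% at room temperature), Prevotellaceae (4.33% and 4.6%), Odoribacteraceae (0.622% and 0.891%) and Anaeroplasmataceae did not pass. The last held 0.525% (0.293% without cold 4) and 0.683% (0.421% without room temperature 2).

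Of 53 families tested at day 31, 23 were higher and 8 lower in cold. Of the 15 fixed families tested, 5 were higher and 6 lower, and the same counts held when adjusted over the list alone. Lachnospiraceae and S24-7 separated all 8 cold libraries from all room temperature libraries (exact permutation, adjusted p = 0.00588 each), Ruminococcaceae 7 of 8 (adjusted p = 0.00882) and Erysipelotrichaceae 7 of 8 (adjusted p = 0.0176). Dehalobacteriaceae (0.374% ± 0.157 against 0.154% ± 0.114, adjusted p = 0.0324), Desulfovibrionaceae (0.842% ± 0.251 against 0.383% ± 0.328, adjusted p = 0.0340) and Bacteroidaceae (1.45% ± 0.509 against 2.69% ± 0.875, adjusted p = 0.0252) passed less firmly. Adjusted p reached 0.0710 for Dehalobacteriaceae without cold 2 or 5 or room temperature 1, 3 or 6, and 0.0794 on centred log-ratios. For Desulfovibrionaceae it reached 0.0738 without cold 2 or 5 or room temperature 1, 3, 4 or 6, and for Bacteroidaceae 0.0573 without room temperature 1, 3 or 4. With taxa of any share included, the 3 adjusted p were 0.0670, 0.0688 and 0.0503. By edgeR on summed counts 3 fixed families were higher and 8 lower, with Dehalobacteriaceae and Desulfovibrionaceae not past and Odoribacteraceae and Rikenellaceae lower. Odoribacteraceae also passed the exact test without cold 4 (adjusted p = 0.0121) and on centred log-ratios (adjusted p = 0.0212).

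**Figure D3:**
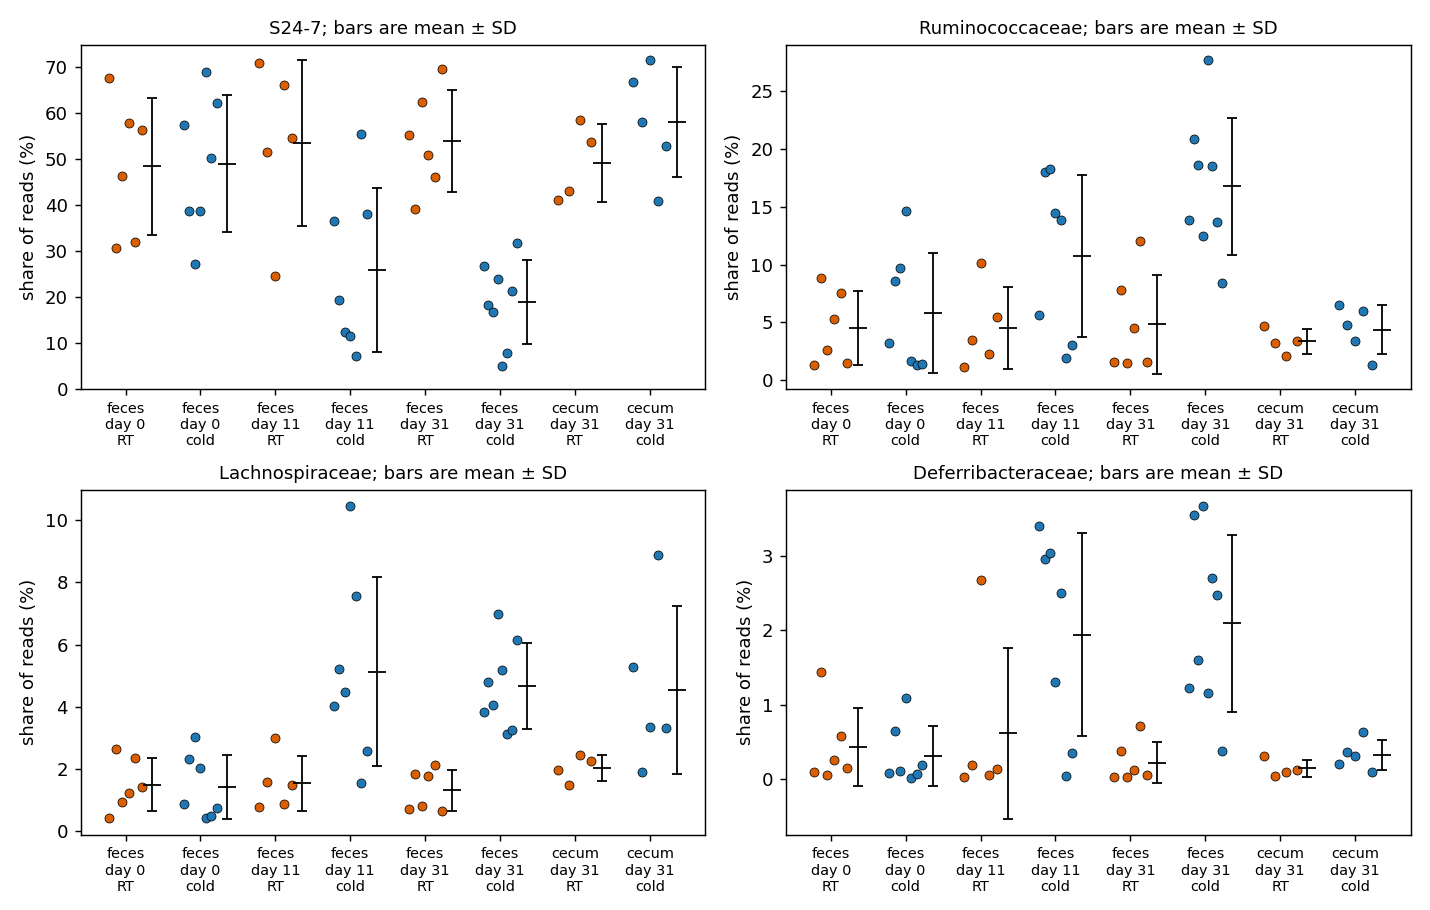
The vertical axes give the share of a library's reads (%) of S24-7, Ruminococcaceae, Lachnospiraceae and Deferribacteraceae, with 1 point per library (orange, room temperature; blue, cold), group means and SD as bars, and the 8 groups along the horizontal axes. In feces at day 31, S24-7 averaged 19.0% in cold and 53.9% at room temperature, and Ruminococcaceae 16.7% and 4.84%.

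Among genera with a name at day 31, Oscillospira, a Ruminococcaceae genus, was 3.14-fold higher in cold at 10.5% ± 3.12 against 3.33% ± 3.38 (adjusted p = 0.0112; 4.89-fold without room temperature 5), and Mucispirillum was higher too (adjusted p = 0.00799). Akkermansia, Allobaculum, Sutterella and Parabacteroides were lower (adjusted p = 0.00423 each), with all 8 cold libraries below every room temperature library. Allobaculum, lower at day 0 already though not past adjustment, had 1 read in the 8 cold libraries and 3366 in the 6 others, and Sutterella held 0.133% and 1.02%. Bilophila was at 0.790% ± 0.257 and 0.328% ± 0.298 (adjusted p = 0.0260), a call lost without room temperature 1, 3 or 6 (adjusted p up to 0.0594). The lower share of Bacteroides (adjusted p = 0.0240) was lost without room temperature 1 or 3 (adjusted p up to 0.0559) and on centred log-ratios (adjusted p = 0.121). The higher share of Dehalobacterium (adjusted p = 0.0316) was lost without cold 6 or room temperature 1, 3 or 6, with adjusted p up to 0.0691. That of the bracketed genus Ruminococcus (0.797% ± 0.436 and 0.289% ± 0.188, adjusted p = 0.0386) was lost without cold 1, 3, 4, 6 or 7 or room temperature 1, 3, 5 or 6, with adjusted p up to 0.0795. Of 108 genera and genus clusters, 28 were higher and 31 lower.

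The fixed lists, made up in part of the families and genera above, were tested at day 31 too. Clostridiales that make short-chain fatty acids held 21.4% ± 5.80 in cold against 6.15% ± 4.90 (exact permutation p = 0.000666, the smallest possible, adjusted p = 0.002), and butyrate-linked genera 10.6% ± 3.12 against 3.47% ± 3.40 (adjusted p = 0.00749; 2.28% at room temperature without library 5). The latter were almost wholly Oscillospira, while Coprococcus held 0.0906% and 0.141% and did not pass. Mucin degraders were lower (adjusted p = 0.002), as were facultative anaerobes and pathobionts, at 0.141% ± 0.0602 against 1.03% ± 0.432 (adjusted p = 0.002), almost wholly Alcaligenaceae. Of the reads of this last list, 927 of 977 in cold and 5326 of 5347 at room temperature were of the genus Sutterella. The list therefore does not show a fall of facultative anaerobes in general. Sulfate reducers were higher at 0.842% against 0.383% (adjusted p = 0.0312), a call that ended (adjusted p up to 0.0727) without cold 3, 4 or 5 or room temperature 1, 3, 4 or 6. Most of these reads, 5492 of 5853 in cold and 1711 of 1995 at room temperature, were of Bilophila, known for using sulfite from taurine rather than sulfate. Lactic acid bacteria held 0.0155% and 0.0313% (exact permutation p = 0.167). Plant and host organelles, diet-borne Lactococcus and reagent taxa had group means of at most 0.0046%, 0.000493% and 0.0638% (0.0368% without cecum cold 6) and passed in no comparison of cold with room temperature.

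Among 272 OTUs tested at day 31, 58 were higher and 50 lower in cold. Of 181 Firmicutes OTUs 57 were higher and 3 lower, and of 83 Bacteroidetes OTUs 0 were higher and 44 lower. S24-7 had 34 lower of 60 and 0 higher, Ruminococcaceae 19 higher of 60 and 0 lower, and Lachnospiraceae 9 higher of 26 and 0 lower, in the same direction under plain TMM and library totals. The OTU of Akkermansia muciniphila (OTU4306262) was lower by -12.46 ± 1.22 (log2, SE). Mucispirillum schaedleri (OTU1136443) was higher by 3.24 ± 0.765, at 2.09% against 0.218% (0.120% without room temperature 5). A Ruminococcaceae OTU (OTU177271) was higher by 2.90 ± 0.764 and the Firmicutes OTU260156 by 4.66 ± 1.14 (2.72 without cold 6). The S24-7 OTU38278 was lower by -9.75 ± 1.35, with 4.48% at room temperature, and the S24-7 OTU185550 by -3.54 ± 0.650, at 0.574% against 4.02%. In Rikenellaceae, whose total share did not pass the exact test, OTU4476780 was lower by -4.91 ± 0.828 and OTU270391 by -3.49 ± 0.580. The most abundant S24-7 OTU named, OTU177115, was lower by -1.72 ± 0.548, at 5.60% against 12.2%, a call lost without room temperature 1 or 6 (-1.48 and -1.77), with library totals only or with no filter.

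Scaling shifted the OTU results at day 31. The median log2 fold change over all tested OTUs was 0.886 with TMMwsp, 0.503 with plain TMM and 1.1 with library totals only, and the calls were 58 higher and 50 lower, 38 and 56, and 47 and 38. With no filter 59 were higher and 157 lower, 60 of the 108 among them, and with a single fit over all groups 69 and 128, so the balance of directions depended on these settings. The count of 108 fell to 56 without room temperature 1 or 6, to 71 without room temperature 2, to 62 without room temperature 3 and to 65 without room temperature 4. Of 230 OTUs tested at both days, 5 were higher in cold at both day 11 and day 31, of 10 and 49 (2.13 expected, Fisher's exact p = 0.0386), and 7 were lower at both, of 11 and 40 (1.91 expected, p = 0.000573), in samples of both days that bear the same numbers and may come from the same mice. Fisher's test takes OTUs as independent, which OTUs of the same samples need not be, so its p-values do not measure how reproducible this overlap is. The community R2 was 0.408 (exact permutation p = 0.000333, the smallest possible, adjusted p = 0.00133). Richness was 706 ± 109 OTUs in cold and 641 ± 104 at room temperature (exact permutation p = 0.289), and the Shannon index 4.32 ± 0.236 and 4.08 ± 0.322 (p = 0.131). Neither measure differed beyond the spread at day 0, at day 11 or in cecum (lowest exact permutation p = 0.579).

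**Figure D4:**
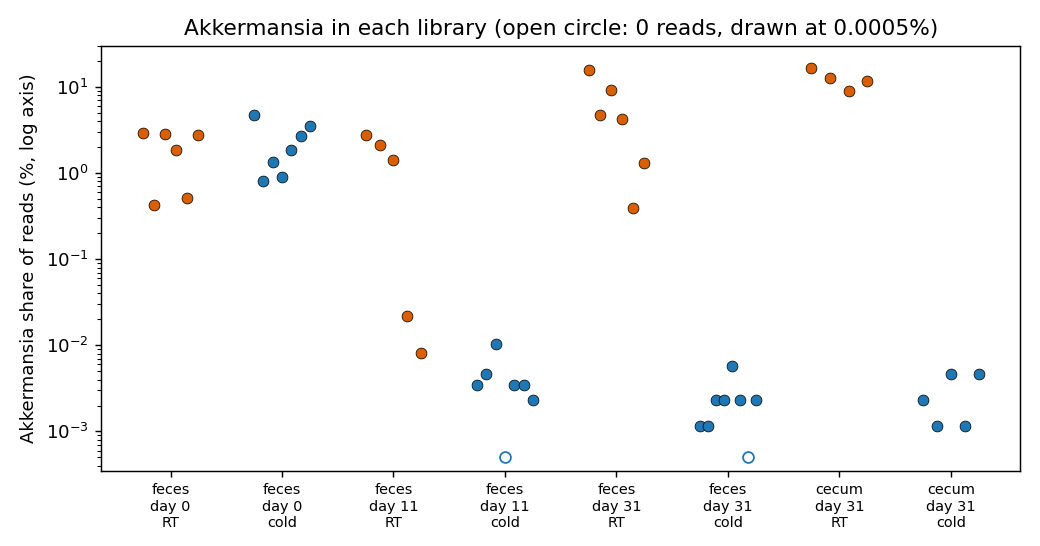
The vertical axis gives the share of a library's reads (%, log axis) held by Akkermansia, with 1 point per library (orange, room temperature; blue, cold; open circles, 0 reads, drawn at a nominal level) and the 8 groups along the horizontal axis. The 20 cold libraries of days 11 and 31 hold between 0 and 9 reads each.

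In cecal content at day 31, Verrucomicrobia were 4525-fold lower in cold, with 12 reads in 5 libraries (0.00276% ± 0.00175) against 43442 reads in 4 (12.5% ± 3.18). Here too the cold mean lay under the floor of 3 reads per library, so the size of the fold is uncertain. Firmicutes held 25.7% ± 9.99 in cold and 22.0% ± 2.05 at room temperature, and Bacteroidetes 72.3% ± 9.96 and 63.6% ± 2.68, within the spread of the libraries (exact permutation p = 0.540 and 0.175, two-sided). S24-7 held 58.0% ± 12.0 and 49.1% ± 8.39, Lachnospiraceae 4.54% and 2.04% (exact permutation p = 0.0635), and Alcaligenaceae 0.464% and 0.999%. Allobaculum had 0 reads in cold and held 0.723% ± 0.792 at room temperature (0.429% without room temperature 2). The log2 ratio of Firmicutes to Bacteroidetes differed by -0.02 (-1.56 ± 0.745 against -1.54 ± 0.143, exact permutation p = 0.968).

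With 5 cold and 4 room temperature mice the smallest possible exact p was 0.0159, which Verrucomicrobia reached with 5 of 5 cold libraries below every other (adjusted p = 0.111 over 7 phyla). Alcaligenaceae reached it too (adjusted p = 0.122). By the exact permutation test 0 of 16 fixed families passed, 0 when adjusted over the list alone, and 0 of 46 families and 0 of 98 genera in all, with 12 and 36 at an unadjusted p under 0.05. By edgeR on summed counts 5 of 46 families passed, of which Verrucomicrobiaceae and Lactobacillaceae, both lower in cold, were in the fixed list. Lactobacillaceae held 0.0550% and 2.03% (1.2% without room temperature 3), with 2 of 5 cold libraries below every room temperature library (exact permutation, adjusted p = 0.243). None of the lists passed, with mucin degraders and facultative anaerobes and pathobionts (0.468% and 1.0%) at an adjusted p of 0.0714, and Clostridiales that make short-chain fatty acids at 8.92% and 5.39% (exact permutation p = 0.127).

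Among 283 cecal OTUs tested with edgeR, 4 were higher and 19 lower in cold. Bacteroidetes had 1 higher and 9 lower of 104, and Firmicutes 3 higher and 8 lower of 163. Akkermansia muciniphila (OTU4306262) was lower by -12.35 ± 0.658 (log2, SE). The S24-7 OTU174573 was higher by 3.49 ± 0.506, at 8.22% against 0.658%. Other S24-7 OTUs were lower, OTU215495 by -2.31 ± 0.289 (1.95% against 8.16%, lost with no filter) and OTU38278 by -5.72 ± 0.997, and OTU321735 was at least 316-fold lower, with 0 reads in cold and 1.09% at room temperature (0.677% without room temperature 2), taken against 3 reads per library. A Lactobacillus OTU (OTU4428313) was lower by -6.33 ± 1.5, a call lost without room temperature 4 or cold 2, 4 or 6 (-6.34 to -5.9). The count of 23 rose to 36 without room temperature 3. DESeq2 called 31 higher and 48 lower, edgeR with no filter 40 and 49, and a single fit over all groups 16 and 40. Fewer were called with a minimum count of 50, at 3 and 12, and with blocks by number, at 0 and 1. Such a block joins a cold and a room temperature mouse, which are different animals. Only 3 numbers occur in both cecal groups, and their profiles did not pair (mean correlation -0.177). The drop with these blocks therefore says little about the calls. Of 185 OTUs tested in feces and cecum, 10 were lower in cold in both, of 48 and 10 (2.59 expected, Fisher's exact p = 6.47e-07), and 2 were higher in both, of 26 and 4 (0.562 expected, p = 0.0955), in samples that came in part from the same animals. As OTUs of the same samples need not be independent, these Fisher p-values do not measure how reproducible the overlap is. The community R2 was 0.508 (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0159).

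Over time in cold feces, more Firmicutes OTUs were called as risen than as fallen from day 0, and more Bacteroidetes OTUs as fallen than as risen. At day 31, 71 of 159 Firmicutes OTUs rose and 9 fell, and 3 of 80 Bacteroidetes OTUs rose and 51 fell, among them 38 of the 56 of S24-7. Ruminococcaceae had 23 OTUs up and 1 down of 55, and Lachnospiraceae 12 up and 0 down of 23. Mucispirillum schaedleri (OTU1136443) rose by 2.56 ± 0.729 (log2, SE) from 0.314% (0.186% without day 0 cold 4) to 2.09% and the Firmicutes OTU179265 by 8.67 ± 1.37 to 4.25%. The S24-7 OTU177115 fell by 2.35 ± 0.532 from 20.2% to 5.60%, OTU215495 of S24-7 by 3.88 ± 0.482, and a Prevotella OTU (OTU4378740) from 8.22% to 4.33%, the last a call lost with library totals only. Its family Prevotellaceae fell as much at room temperature, by -4.5 percentage points per number against -4.48 in cold (exact permutation p = 0.965). At day 11, 33 of 134 Firmicutes OTUs had risen and 12 fallen, and 7 of 84 Bacteroidetes OTUs had risen and 22 fallen. The S24-7 OTU203713 had risen by 2.28 ± 0.652 to 3.84% by then (1.63 without day 11 cold 7), a call lost with no filter.

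In all, 41 OTUs were higher and 35 lower of 226 at day 11 against day 0 in cold feces, and 75 higher and 63 lower of 247 at day 31. At room temperature 2 were higher and 0 lower of 230 at day 11 (37 at an unadjusted p under 0.05, 21 by DESeq2), and 8 higher and 1 lower of 210 at day 31. The S24-7 OTU174573 rose at room temperature by 3.0 ± 0.547 to 2.85% at day 11, and the S24-7 OTU38278 by 5.16 ± 0.821 to 4.48% at day 31 (4.41 without day 31 room temperature 6). Single libraries decided the room temperature counts. That of day 11 was 6 without day 11 room temperature 1, 17 without day 11 room temperature 3 and 1 without day 0 room temperature 5. That of day 31 ranged from 2 without day 31 room temperature 6, 3 without 3 and 4 without 4 to 16 without day 31 room temperature 1 and 14 without day 0 room temperature 1 or 5. In cold feces plain TMM gave 33 higher and 37 lower at day 11 and 87 and 62 at day 31, no filter 81 and 99, and 142 and 180, and a single fit over all groups 85 and 86, and 135 and 144. At room temperature no filter gave 45 higher and 6 lower at day 11 and 44 and 11 at day 31. The single fit gave 5 and 1 there at day 11 and 27 and 6 at day 31.

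The change from day 0 to day 31 per sample number differed between temperatures in 4 phyla. Firmicutes rose by 43.6 ± 22.0 percentage points in cold (7 of 7 numbers up) and changed by -1.12 ± 4.88 at room temperature (2 of 6 up), a difference of 44.7 (exact permutation p = 0.00117, the smallest possible, adjusted p = 0.00272). Bacteroidetes fell by 43.8 ± 21.4 in cold against -3.18 ± 7.79, and Deferribacteres rose by 2.03 ± 0.750 against -0.213 ± 0.426 (adjusted p = 0.00272 each). Verrucomicrobia fell by 2.29 ± 1.48 in cold, in 7 of 7, against a mean change of 4.07 ± 5.18 at room temperature (2.3 without number 1), with 4 of 6 up (adjusted p = 0.00816). Among families, 8 of 15 differed, including S24-7 at -31.9 ± 18.7 against 5.49 ± 12.0 (adjusted p = 0.0117), Lachnospiraceae at 3.05 against -0.187 (adjusted p = 0.00874) and Ruminococcaceae at 12.1 against 0.336 (adjusted p = 0.0153). Leaving out 1 number moved none of these differences between temperatures by over 1.5 times, but it moved most of the room temperature means, which lay nearer 0. Some families lower in cold at day 31 did not pass in this change (exact permutation). These were Bacteroidaceae (-2.57 against -2.18, adjusted p = 0.991), Porphyromonadaceae (-0.21 against -0.14, adjusted p = 0.612) and Erysipelotrichaceae (-0.06 against 0.38, adjusted p = 0.229). From day 0 to day 11, 0 of 16 families passed the exact permutation test, with 2 at an unadjusted p under 0.05, S24-7 at -21.9 against 6.96 and Lachnospiraceae at 3.96 against -0.0145 (adjusted p = 0.208 each).

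The interaction of temperature with time was called for 5 OTUs with a higher and 38 with a lower change in cold at day 11, of 378, and for 12 and 57 of 375 at day 31. At day 31 the lower changes included 39 of 107 Bacteroidetes OTUs, 28 of them S24-7, and Akkermansia muciniphila (OTU4306262) by -12.25 ± 1.39 (log2, SE). Firmicutes had 11 higher and 15 lower of 259. With the number within a temperature as a block, 20 and 55 OTUs were called. DESeq2 called 67 and 106, and without day 31 room temperature 5 the count of 69 rose to 116.

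Cecum and feces, whose DNA was also isolated differently, were compared at day 31 in each temperature. In cold mice S24-7 OTUs were higher in cecum, 40 of 60 with 0 lower, and Ruminococcaceae OTUs were mostly lower, 6 higher and 31 lower of 69. The S24-7 OTU174573 was higher in cecum by 2.15 ± 0.427 (log2, SE), at 8.22% against 2.38%, and OTU203713 of the same family by 2.00 ± 0.470. Mucispirillum schaedleri (OTU1136443) was lower by -2.26 ± 0.681, at 0.319% against 2.09% (lost with no filter), and the Firmicutes OTU4418586 by -6.55 ± 1.37. In room temperature mice the calls fell mainly on Firmicutes, with 9 higher and 11 lower of 151. A Lactobacillus OTU (OTU4428313) was higher in cecum there by 6.79 ± 1.59, and an Anaeroplasma OTU (OTU4390755) was lower by -5.22 ± 1.23. The first call was lost without cecum room temperature 3 or 4 (6.27 and 6.32) and the second without cecum room temperature 2, 3 or 4 (-4.95, -4.82 and -4.86) or with a minimum count of 50. None of the 8 OTUs examined by name at room temperature kept its call with each library left out.

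In cold mice 71 OTUs were higher and 71 lower in cecum of 318, and 111 and 118 with cecum and feces of the same number paired, which kept 141 of the 142. In room temperature mice 11 were higher and 13 lower of 272, and 20 and 27 when paired, which kept 23 of the 24. In cold mice library totals gave 48 higher and 84 lower, with a median log2 fold change of -0.244 against 0.115 by TMMwsp, while no filter gave 138 higher and 63 lower and a single fit over all groups 123 and 96. The room temperature count of 24 fell to 5 without cecum room temperature 2 and to 2 without cecum room temperature 3 or 4. It was 0 of 138 tested with a minimum count of 50.

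The step from feces to cecum differed between temperatures. Per sample number, Firmicutes were lower in cecum than in feces by -40.1 ± 4.42 percentage points in 5 of 5 cold mice, and differed by 5.77 ± 9.33 at room temperature, with 3 of 4 higher. Bacteroidetes were higher in cecum by 43.0 ± 4.44 in 5 of 5 cold mice and differed by -8.70 ± 6.04 at room temperature, lower in 4 of 4. Deferribacteres differed by -2.22 ± 1.28 in cold and 0.00748 ± 0.258 at room temperature. The exact permutation p was 0.0159, the smallest possible, for each of the 3 phyla (adjusted p = 0.0423), and 0 of 18 families passed, with 6 at an unadjusted p under 0.05, among them S24-7 at 43.6 against -2.85 and Ruminococcaceae at -15.2 against -0.502 (adjusted p = 0.0952 each). Leaving out 1 animal moved none of these differences between temperatures by over 1.5 times, but it moved the room temperature means of Firmicutes (2.59 without 3 to 9.33 without 2), Deferribacteres, S24-7 and Ruminococcaceae. No phylum passed with 1 animal left out, since the smallest p of the smaller groups cannot pass adjustment. At the rank of OTU the unpaired edgeR interaction called 0 of 479, with 74 at an unadjusted p under 0.05 and 29 by DESeq2. With the animal as a block edgeR called 71 OTUs relatively higher in cecum of cold mice and 9 lower, of which 54 higher were among the 94 OTUs of S24-7 and 0 of these were lower.

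**Figure D5:**
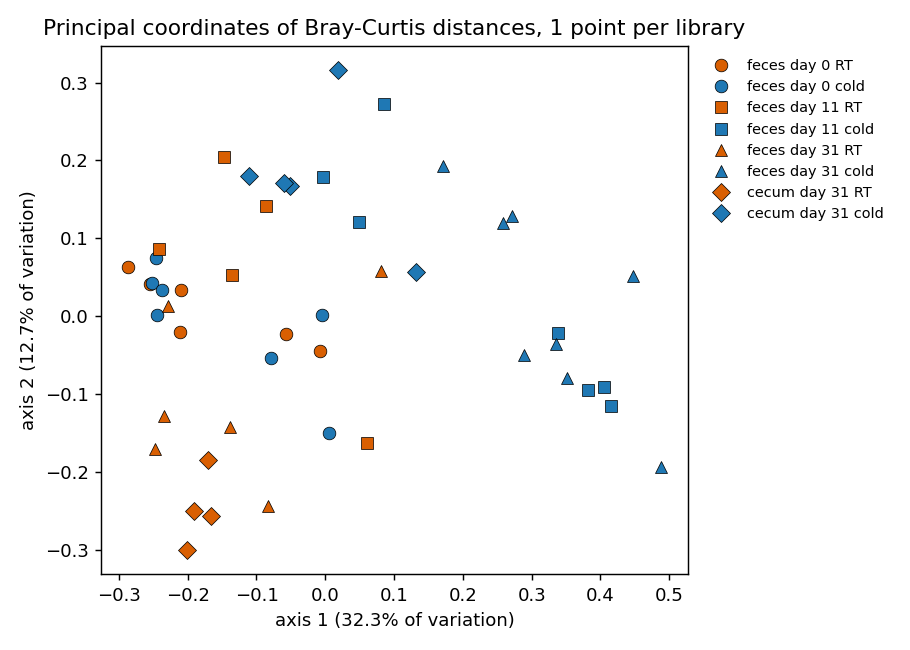
Principal coordinates of Bray-Curtis distances between the 48 libraries, with 1 point per library (orange, room temperature; blue, cold; the marker shape gives site and day), where the horizontal axis holds 32.3% and the vertical axis 12.7% of the variation. Cold feces of day 31 lie to the right, and temperature took an R2 of 0.408 in feces and 0.508 in cecum at day 31.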

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

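The tests of 1 factor per phylum, of both explanations for the remaining Akkermansia reads and of other splits for the interactions with time were chosen after the results were seen, as was the exact test of cecum minus feces per number.

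Cold and room temperature mice differed in Firmicutes and Bacteroidetes in feces and not detectably in cecum at day 31, and the step from feces to cecum differed between temperatures by -45.8 percentage points for Firmicutes, 51.7 for Bacteroidetes and -2.22 for Deferribacteres, with 80 OTUs called in the interaction with the animal as a block. DNA isolation that multiplies each phylum by 1 factor would shift cecum against feces alike in both temperatures. But the log2 ratio of Firmicutes to Bacteroidetes moved by -2.78 ± 0.296 in 5 cold mice and 0.87 ± 1.07 in 4 room temperature mice. The difference was -3.66 (exact permutation p = 0.0159, the smallest possible). It restates the pattern per animal and is no further test, but 1 factor per phylum alone cannot give it. For a factor per OTU, the step of the median Firmicutes OTU minus that of the median Bacteroidetes OTU differed by -3.08 between temperatures (exact permutation p = 0.0159). Cold and room temperature mice differed in their OTUs, so such factors could give this too. Of 100 reassignments of temperature over the animals, the real one included, 1 called as many as 80 OTUs, with 37 the highest other. Those calls rest on the scaling of libraries that differ in composition, so a factor per OTU was not settled. The choice of animals is argued against by the feces as a whole, where all 8 cold libraries lay above every room temperature library in the ratio of Firmicutes to Bacteroidetes. Any choice of animals therefore keeps a difference in feces, and the 3.63 of the animals that gave cecum follows from this and is no further test. A DNA isolation whose bias depends on the sample, or a response to cold that differs between cecum and feces, could each stay behind the pattern, and neither was tested.

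Akkermansia kept a few reads in the cold libraries of days 11 and 31, 51 in 20 libraries with 0 to 9 in each, which is 0.0491% of all its reads. If these were carried over from other libraries at 1 rate, counts would scatter like Poisson counts. Over the 20 libraries the ratio of variance to mean was 1.63, above the scatter of 100000 Poisson simulations at the threshold of 0.05. It was 0.884, within that scatter, without feces day 11 cold 3, whose count was the highest, so this stays open. Allobaculum had 2 reads in these libraries where carry-over in proportion to its other reads gives 4.3 (exact two-sided binomial p = 0.321). This does not argue against such carry-over, but so few reads test it weakly and reads are not independent, so it stays open. A small remaining population may equally hold these reads, which was not tested.

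The change from day 0 differed between temperatures for 43 OTUs at day 11 and 69 at day 31. A chance division of the libraries is argued against at day 31, where 1 of 100 splits gave as many as 69, the real one included. It is argued against only weakly at day 11, where 3 of 100 gave as many as 43, the real one included. At day 11 another split called 108 OTUs, more than the real 43. It may point to a structure of the samples, which was not tested. The highest other at day 31 was 49. With the number within a temperature as a block, 20 and 55 OTUs were called.

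Shares of phyla and families also differed in their change from day 0 to day 31, by an exact permutation test of cold minus room temperature. Among phyla the differences were 44.7 percentage points for Firmicutes, -40.6 for Bacteroidetes, -6.36 for Verrucomicrobia and 2.24 for Deferribacteres. Families differed by -37.3 for S24-7, 3.23 for Lachnospiraceae, 11.8 for Ruminococcaceae, 0.325 for Dehalobacteriaceae, 0.440 for Desulfovibrionaceae and -0.650 for Alcaligenaceae.

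Single libraries lay far from the rest of their group in 6 of 88 tests of a group and measure, and chance gives about 1 in 20. Feces day 31 cold 4 had 946 OTUs against 595 to 758 in the other 7 libraries. Verrucomicrobia held 0.00576% of feces day 31 cold 5 (5 reads, 95% Wilson interval 0.00246% to 0.0135%) against 0 to 0.00230%. Deferribacteres held 2.68% of feces day 11 room temperature 3 (2.57% to 2.79%) against 0.0265% to 0.185%. Proteobacteria held 1.93% of feces day 11 room temperature 2 (1.85% to 2.03%) against 0.596% to 0.897%. They held 3.21% of feces day 11 cold 8 (3.10% to 3.33%) against 0.653% to 1.27%. In feces day 31 room temperature 1 they held 1.85% (1.76% to 1.94%) against 1.29% to 1.46%.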

How the results depend on the processing

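Chosen after the data were seen were richness at 43438 reads, the alternatives for single taxa, folds, mean shares and mean changes with 1 library or number left out, and leaving out libraries in the interactions with time, in the change from day 0 and in cecum minus feces. Over the comparisons, 112 of 162 values under other settings kept their direction and side of the threshold (counts within 1.5 times), 1 was weaker, 1 stronger, 45 moved and 3 reversed. With 1 library left out 450 of 519 kept it, 1 was weaker, 1 stronger, 47 moved and 20 reversed. Of 564 values of named OTUs under other settings, 498 stayed past the threshold and 0 reversed, and blocks by number lost the most, 27 of 83. In comparisons of cold with room temperature these blocks join different mice, so a loss there says little about the call. Of 90 values of taxa past the threshold, 71 stayed past, 18 were weaker and 1 reversed, Proteobacteria at day 31 on centred log-ratios (0.234, adjusted p = 0.371). The reference of those ratios is lowered in cold by the near absence of Verrucomicrobia. With 1 library left out, 163 of 1012 values of named OTUs and 87 of 434 values of taxa were weaker, and 0 reversed. The named OTUs were picked for passing in these same libraries, which makes reversals unlikely from the start. Their lack of reversals, here and under other settings, is therefore no independent support. Richness at full depth equals the main value because all depths are equal, so that alternative was void. In simulated data at the day 31 sizes, changes of 4-fold were recovered in 0% and of 16-fold in 63.6%. The simulation took its spread from all OTUs before the filter and without scaling, unlike the real fit. At day 31 the real fit called OTU177115 at a change under 4-fold. These shares are therefore not the detection limit of the real data, and low counts of OTUs do not bound smaller changes. Unless a reason is given, the cause was not tested.

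Without a filter, more OTUs were tested and edgeR called 2 at day 0, 83 at day 11 (27 in the report), 216 at day 31 (108) and 89 in cecum (23). It called 180 (76) and 322 (138) over time in cold feces, 51 (2) and 55 (9) over time at room temperature, 63 (24) for site at room temperature, and 5 (0) for the interaction with site. A minimum count of 50, which tests fewer OTUs, gave 15 in cecum, 34 and 84 over time in cold, 6 at day 11 over time at room temperature, 0 and 86 for site at room temperature and in cold, 28 for the interaction with time at day 11 and 10 for that with site. A single fit over all groups gave 113 at day 11, 197 at day 31, 56 in cecum, 171 and 279 over time in cold, 6 and 33 at room temperature, and 43 and 219 (142) for site. DESeq2 gave 66 at day 11, 79 in cecum, 21 over time at room temperature at day 11, 50 for site at room temperature, 67 (43) and 106 (69) for the interactions with time and 29 for that with site. Blocks by number gave 14 at day 11, 1 in cecum, 4 over time at room temperature at day 31, 47 and 229 for site and 10 for the interaction with site. At day 11, in cecum and in that interaction they joined cold and room temperature mice of the same number, which are different animals. Blocks by animal gave 80 for the interaction with site and 20 for the interaction with time at day 11.

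Leaving out 1 library gave 14 to 37 OTUs at day 11 (14 without room temperature 1, 15 without cold 4) and 56 to 144 at day 31 (56 without room temperature 1 or 6, 71 without 2, 62 without 3, 65 without 4). It gave 17 to 36 in cecum (36 without room temperature 3), 1 to 17 over time at room temperature at day 11 (1 without day 0 number 5, 6 without day 11 number 1, 17 without day 11 number 3) and 2 to 16 at day 31 (2, 3 and 4 without day 31 numbers 6, 3 and 4, 16 without day 31 number 1, 14 without day 0 number 1 or 5). For site at room temperature it gave 2 to 24 (5, 2 and 2 without cecum 2, 3 and 4). For the interaction with time at day 31 it gave 49 to 116 (116 without day 31 room temperature 5). For that with site it gave 0 to 3 (3 without fecal room temperature 2 or 5, 2 without fecal room temperature 4, fecal cold 5 or cecal cold 6).

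With reads outside Verrucomicrobia as the denominator, Lactobacillaceae at day 11 had an adjusted p of 0.0530, with a 23.6-fold difference (23.1 in the report), and Verrucomicrobiaceae cannot be tested that way. The 2 fixed families past the threshold at day 11 became 0 with taxa of any share, and 0 to 0 with 1 library left out. In cecum edgeR on summed counts called 2 fixed families, of 5 families in all, where the exact test called 0. The 3 phyla of cecum minus feces became 0 with 1 animal left out, as the smallest p of the smaller groups cannot pass.

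Verrucomicrobia at day 0 differed by -0.0154 (without cold 1) to 0.644. As Lachnospiraceae plus Ruminococcaceae over S24-7, the log2 ratio differed by 0.0357 at day 0 (p = 0.983, exact permutation), 2.66 at day 11 (p = 0.048) and 0.383 in cecum (p = 0.492). With 1 library left out the log2 ratio of phyla differed by -0.551 to 0.149 at day 0 (above 0 without cold 5, 6 or 7 or room temperature 2 or 5), by 1.62 to 2.55 at day 11 (2.53, exact permutation p = 0.0303, without cold 7) and by -0.287 to 0.155 in cecum (above 0 without cold 2, 3 or 4 or room temperature 4). Richness differed by -3.33 to 40.8 at day 0 (below 0 without cold 2, 3 or 4 or room temperature 1 or 6), -0.6 to 50.7 at day 11 (below 0 without cold 6) and -0.5 to 72.9 in cecum (below 0 without cold 4). Shannon diversity differed at day 11 by -0.0366 over genera and by -0.0364 to 0.146 with 1 library left out (below 0 without room temperature 1 or 5), and in cecum by -0.131 to 0.0206 (above 0 without cold 6). Apart from the day 11 ratios of 2.66 and 2.53, these differences lay within the spread of the libraries. The community R2 at day 11 was 0.239 on family shares (exact permutation p = 0.0543) and 0.211 to 0.300 with 1 library left out (0.211, exact permutation p = 0.0515, without room temperature 1).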

Other observations

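The tests of other splits of the libraries given here were all chosen after the counts of OTUs were seen.

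These are values of 3 genera by site and day, for which no test between sites was made at the rank of genus. Adlercreutzia, of the family Coriobacteriaceae, held 0.177% ± 0.105 of cecal reads in cold mice (n = 5) and 0.152% ± 0.0811 at room temperature (n = 4), against 0.00590% ± 0.00264 (n = 8) and 0.00998% ± 0.00416 (n = 6) in feces at day 31. Lactobacillus held 2.03% ± 2.30 of cecal reads at room temperature (1.2% without room temperature 3) and 0.0550% ± 0.0266 in cold. Prevotella held 9.10% ± 3.38 and 8.22% ± 3.82 of fecal reads at day 0 in the groups assigned to room temperature and cold, and 4.6% ± 2.02 and 4.33% ± 2.86 at day 31, with 2.24% ± 1.52 and 5.53% ± 2.77 in cecum.

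Akkermansia reads varied within room temperature feces. At day 11 the libraries of numbers 1, 2 and 3 held 2412, 1854 and 1235 reads, and those of numbers 5 and 6 held 19 and 7. At day 31 the 6 libraries held 338 to 13769 reads.

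Other splits of the same libraries, 100 for each comparison with the real one included, were counted with edgeR to see how often they call as many OTUs. For cold against room temperature the real counts of OTUs were 27 at day 11, 108 at day 31 and 23 in cecum. The highest other counts were 6, 18 and 6, and 1 split of 100 gave as many. A chance division of the libraries is argued against by this, but the splits cannot tell temperature from cage. At day 0 the count was 0, which all 100 splits reach, with 0 the highest other. Over time in cold feces the real counts were 76 and 138 and the highest others 41 and 2, with 1 of 100 as large each. At room temperature the real count at day 11 was 2, with 3 of 100 as large and 16 the highest other. That other split may point to a structure of the samples, which was not tested. At day 31 the real count was 9, with 1 of 100 as large and 3 the highest other. For cecum against feces the real counts were 24 at room temperature and 142 in cold, with 6 and 2 the highest others and 1 of 100 as large each. Among splits that part every pair of cecum and feces, 1 of 32 reached 142 in cold, with 11 the highest other, and at room temperature the 16 splits are too few for a share under 0.05, with 24 the real count and 0 the highest other. For the unpaired interaction of temperature with site the count was 0, which all 100 splits reach, with 19 the highest other.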
